A study of Homo sapiens with 9 samples.

How the data were processed

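The series holds 9 RNA-seq libraries of 22Rv1 prostate cancer cells, 3 per group, with the groups and replicate numbers taken from the sample titles. Per the labels' protocols, RNA was isolated with a column kit and libraries were made with a stranded total RNA kit that removes ribosomal RNA, so that transcripts without a poly(A) tail, such as replication-dependent histone transcripts, are kept. The authors deposited 1 table of counts per gene for all libraries, with whole numbers that have not been normalized. Per the submitters' processing notes, STAR 2.5.2a, featureCounts 1.5.0-p3 and DESeq2 1.14.1 were used with the hg19 genome. Per the file headers, the table gives the exon coordinates, strand and length of each gene in hg19. The strand setting of the counting, the treatment of reads with several matches and the annotation release are not given in the sources used here. Reads from near-identical copies (kallikreins, UGT2B, AKR1C, histones and ribosomal proteins) and from genes with overlapping exons are therefore uncertain. Of the 58 genes taken by rule as fixed genes or largest changes, 12 have exons that overlap those of another tested gene.

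The table has 63677 genes. Symbols were assigned by Ensembl gene identifier from a table of gene names and from GENCODE 29, which belongs to GRCh38 and was used for names, gene types and transcript sequences only. In all 52526 identifiers were matched, which hold 95.7% of the counts. Of 844 entries in the gene lists 17 could not be matched, most of them histones. Totals ran from 21445643 to 27284818 counts. No pair of replicates agreed within sampling noise: the chi-square per degree of freedom between replicates ran from 4.74 to 79.3, with both highest values in pairs with CCS1477 replicate 1. The labels do not say whether replicates came from separate cultures, and p-values measure only the spread between these samples, which may be technical.

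Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with a minimum count of 10, which left 19966, libraries were scaled with TMM factors, and quasi-likelihood models (glmQLFit and glmQLFTest) were fitted to all 9 libraries with 1 term per group. The biological coefficient of variation was 4.68%. P-values are two-sided and were adjusted by Benjamini-Hochberg over all genes tested, with 0.05 as the threshold. Log2 fold changes are given with a standard error derived from the F statistic, and CPM values use the TMM-scaled totals. The comparisons were CCS1477 against control, JQ1 against control and CCS1477 against JQ1. A gene that changed at least 2-fold had an absolute log2 change of 1 or more.

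Before the data were examined, 25 gene lists were fixed, among them broad androgen response, MYC targets, DNA replication, mitosis, homologous recombination, histones, BET inhibitor response markers, interferon response, NF-kappaB and TNF response, cholesterol synthesis, ATF4 and amino acid response, p53 targets, immediate early genes, hypoxia, BCL2 family, androgen metabolism, luminal epithelial lineage, neuroendocrine, basal epithelial, mesenchymal and stromal, and leukocyte markers, ribosomal proteins, the mitochondrial genome, and transcription elongation and bromodomain factors. Some genes belong to several lists. Results for some genes and for 1 list are not reported here. Each list was tested with camera at a preset correlation of 0.01, adjusted over the lists. With an estimated correlation 6 lists kept their call for CCS1477 against control (among them broad androgen response, mitosis, histones, interferon response and luminal epithelial lineage) and 0 in each of the other comparisons. For broad androgen response under CCS1477 that correlation was 0.0143, near the preset 0.01. Its adjusted p by camera still went from 1.42e-16 to 0.00315. A call lost with an estimated correlation is therefore not by itself a sign of correlated members. Counts adjusted over the list alone apply Benjamini-Hochberg within a list. The genes named were also set by rule: 20 fixed genes, the 8 largest rises and 8 largest falls among called genes with a mean of at least 2 CPM over the 9 libraries, no overlap between the libraries of the groups and a symbol that is not a clone name, and up to 4 members of each list with the smallest p. Other genes are named where they illustrate a count and were chosen after their values were seen.

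The models were tested on simulated counts drawn from the means and spread of these libraries with 200 genes changed. For CCS1477 against control, over 19355 genes, 50.0%, 82.0%, 94.0% and 100% of genes changed 1.25-, 1.5-, 2- and 4-fold were called, and 6.32% of calls were false. For JQ1 against control, over 19351 genes, the shares were 62.0%, 82.0%, 100% and 100%, with 6.01% false calls. In the data far more genes were called (8429 under CCS1477 and 12994 under JQ1), and changes of at least 2-fold were mostly downward. These shares of false calls therefore need not hold for the data. In further simulations over 19366 genes for CCS1477 and 19341 for JQ1, a list of 40 genes moved by 1.3-fold was called in both, and 0 of 24 unmoved lists were called in either. Genes were drawn independently there, so this says nothing about false calls of lists with correlated members. In the data the estimated correlation for CCS1477 against control was 0.245 for mitosis and 0.385 for ribosomal proteins.

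The alternatives were RLE, upper-quartile and no scaling factors, other filters, omission of mitochondrial, 7SL, 7SK and ribosomal RNA genes, DESeq2 1.42.0, fits of the compared groups alone, the replicate number as a block, each library left out, other list tests, and protein-coding genes only, the last chosen after seeing the data. Changes under both inhibitors were set against 20 simulated draws without effects, in which all 9 libraries were drawn anew and both comparisons shared the simulated control libraries.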

Results

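RNA was profiled in 22Rv1 cells, an established human prostate cancer cell line. The cells had been kept without hormone for 72 hours and were then exposed for 24 hours to vehicle, to 96 nM CCS1477 or to 100 nM JQ1. Per the labels, CCS1477 inhibits the acetyltransferases p300 and CBP and JQ1 inhibits the BET bromodomain proteins. Each of the 3 groups held 3 libraries. The totals of counted reads ran from 21445643 in CCS1477 replicate 1 to 27284818 in CCS1477 replicate 2, and 19966 genes had enough counts to be tested. Mitochondrial ribosomal RNA took 4.19% of the counts in CCS1477 replicate 1 and between 0.490% and 1.66% in the other 8 libraries. In a multidimensional scaling of the 500 most variable genes per pair of libraries the 3 groups separated, and the first dimension, which held 60.5% of the variance, ran from the control libraries through CCS1477 to JQ1.

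The first comparison asked which transcripts the p300/CBP inhibitor altered. Under CCS1477 androgen-responsive kallikreins fell. KLK3, which encodes prostate-specific antigen (chromosome 19, 51358171 to 51364020, hg19), went from 16.8 ± 1.6 to 1.3 ± 0.27 CPM (counts scaled to library size, mean ± SD, n = 3), a log2 change of -3.70 ± 0.13 (SE). KLK2 beside it (51364824 to 51383823) went from 51.3 ± 3.3 to 6.80 ± 0.42 CPM, a log2 change of -2.92 ± 0.08. TMPRSS2, a serine protease gene on chromosome 21, fell by 2.28 on the log2 scale, and KLK4 fell by 2.13. MYC, the proliferation-associated transcription factor (chromosome 8, 128747680 to 128753674), fell by 1.39 from 184 to 70.2 CPM. All 40 measured genes of the mitosis list rose in the same libraries.

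The broad androgen response list had 53 lower and 16 higher genes of 97 measured (54 and 17 adjusted over the list alone). It differed from the remaining genes by camera (adjusted p = 1.42e-16) and kept the call with an estimated correlation (adjusted p = 0.00315). PMEPA1 (-1.55), INPP4B (-1.33) and the chaperone gene FKBP5 (-0.82) were among those that fell, whereas HERC3 (0.28) and IDI1 (0.42) rose. FOXA1, a pioneer factor, had a log2 change of -0.03 (adjusted p = 0.623).

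In the luminal epithelial list 16 of 22 measured genes fell and 1 rose (16 and 1 adjusted over the list alone), with a median of -0.59 (adjusted p = 2.24e-20, and 0.0143 with an estimated correlation). Keratins KRT19 (-1.47) and KRT18 (-0.68), the ETS factor EHF (-0.99) and HOXB13 (-0.76) were lower. Of the HOXB13 exon bases, 20% are also exons of PRAC2 on the opposite strand. Among 15 measured genes of androgen metabolism 8 fell and 1 rose (8 and 1 adjusted over the list alone), including AKR1C3 (-1.24) and UGT2B15 (-0.68), members of families with close copies. That list was called at an adjusted p = 0.00113, but had an adjusted p = 0.168 with an estimated correlation.

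Cell-cycle genes were higher. Mitosis genes had a median log2 change of 0.56 (40 of 40 also adjusted over the list alone, adjusted p = 1.01e-42, and 0.0143 with an estimated correlation). CDCA3 (0.76), KIF2C (0.64), the anaphase-promoting complex partner UBE2C (0.63) and the kinesin gene KIF11 (0.62) were examples. Of 42 DNA replication genes 38 rose and 1 fell (38 and 1 adjusted over the list alone), among them RRM2 (0.84), a subunit of ribonucleotide reductase, and LIG1 (0.56). This call was at an adjusted p = 2.07e-15, and at an adjusted p = 0.0691 with an estimated correlation. Histone genes rose in 20 of 21 cases (21 adjusted over the list alone, median 0.45, adjusted p = 1.60e-18, and 0.0342 with an estimated correlation), although these genes have near-identical copies. Homologous recombination genes rose in 24 and fell in 2 of 38 cases (24 and 2 adjusted over the list alone; adjusted p = 2.16e-05, and 0.168 with an estimated correlation), among them BARD1 (0.45) and BRIP1 (0.44). Without CCS1477 replicate 1, the library richest in mitochondrial ribosomal RNA, 39 of the 40 mitosis genes and 37 of the 42 DNA replication genes rose.

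MYC targets fell in 41 and rose in 8 of 57 cases (42 and 9 adjusted over the list alone), among them the hexokinase gene HK2 (-1.13) and the nucleolar gene NOP16 (-0.89), with a list adjusted p = 6.81e-10, and 0.168 with an estimated correlation. Of 75 ribosomal protein genes 69 fell and 0 rose (70 adjusted over the list alone), by a median of only -0.20, at an adjusted p = 1.01e-07, and 0.356 with an estimated correlation. The 33 genes of the ATF4 and amino acid response had 24 lower and 4 higher members (25 and 4 adjusted over the list alone), including STC2 (-1.03) and the cystine transporter gene SLC7A11 (-0.68), at an adjusted p = 2.40e-06, and 0.168 with an estimated correlation. Hypoxia genes fell in 14 and rose in 4 of 25 cases (14 and 4 adjusted over the list alone), with NDRG1 at -1.22 and VEGFA at -0.53 (adjusted p = 5.08e-05, and 0.0691 with an estimated correlation). Among p53 targets 12 of 24 fell and 4 rose (13 and 4 adjusted over the list alone; adjusted p = 0.0154, and 0.401 with an estimated correlation). They included GDF15 (-0.91) and the cyclin-dependent kinase inhibitor gene CDKN1A (-0.35).

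Interferon-response genes rose in 20 and fell in 7 of 39 cases (20 and 7 adjusted over the list alone; adjusted p = 0.00118, and 0.0370 with an estimated correlation). OAS3 (1.06) and RSAD2 (1.05) rose while ISG15 (-0.45) fell. Cholesterol synthesis genes rose in 16 and fell in 2 of 26 cases (16 and 2 adjusted over the list alone), with MVD at 0.71 (adjusted p = 0.000275, and 0.330 with an estimated correlation). Transcription elongation and bromodomain genes rose in 16 and fell in 3 of 30 cases (16 and 4 adjusted over the list alone), with BRD2 at 0.39 and CREBBP, which encodes CBP, at 0.28 (adjusted p = 0.0196, and 0.168 with an estimated correlation). Without CCS1477 replicate 2 the change of CREBBP, CCS1477 vs control, was 0.16 (adjusted p = 0.0486), and over the alternatives this adjusted p ran from 2.83e-05 to 0.0486. EP300, which encodes p300, had a log2 change of 0.19 (adjusted p = 0.0193). The EP300 call was lost without control replicate 2 or 3 or without CCS1477 replicate 2 or 3, and the adjusted p ran from 0.00167 to 0.161 over the alternatives. Of 7 markers of BET inhibitor response 4 rose and 0 fell (4 and 0 adjusted over the list alone; adjusted p = 0.00216, and 0.0907 with an estimated correlation), HEXIM1 by 0.42 among them. Some histone genes stand on both this marker list and the histone list, so the calls of these lists are not fully separate.

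Among genes with a mean of at least 2 CPM over the 9 libraries and no overlap between the libraries of the groups, the largest rises belonged to TCEAL2 (1.71), STARD9 (1.57), ZMYND10 (1.55) and the autophagy receptor gene OPTN (1.48), followed by PMP22, PDGFRL, DDX60 and ATRNL1. PDGFRL shares 11.5% of its exon bases with MTUS1 on the opposite strand. By the same limits the largest falls after KLK3 and KLK2 were those of CYP4F8 (-2.71), TUNAR (-2.57), MYBPC1 (-2.56), EDN2 (-2.48), the potassium channel gene KCNMA1 (-2.48) and KRT7 (-2.44). No call was made by camera for NF-kappaB and TNF response genes (6 up, 6 down of 22; adjusted p = 0.892), immediate early genes (12 up, 9 down of 29; 0.429), the BCL2 family (5 up, 7 down of 17; 0.708), neuroendocrine markers (3 up, 4 down of 18; 0.635), basal epithelial markers (0 up, 2 down of 9; 0.827), mesenchymal and stromal markers (3 up, 6 down of 14; 0.429), leukocyte markers (1 up, 1 down of 4; 0.913) or the mitochondrial genome (2 up, 0 down of 13; 0.206). In the leukocyte list the median (0.44) and mean (0.08) were positive while the test pointed down, and in the basal list the median was 0.07 and the mean -0.20. Adjusted over the list alone, the counts of the lists not called were the same except for immediate early genes (12 up, 10 down), mesenchymal and stromal markers (3 up, 7 down) and the mitochondrial genome (1 up, 0 down).

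In all, 8429 of 19966 genes changed under CCS1477 (4290 higher, 4139 lower) by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and 864 of these changed at least 2-fold, 198 upward and 666 downward. With library totals as the only scaling the split was 4801 higher and 3234 lower. The libraries of the groups did not overlap for 9955 genes (49.9%, where chance gives 10%). The call for transcription elongation and bromodomain factors was lost when protein-coding genes alone were tested (adjusted p = 0.0718), and over the alternatives this adjusted p ran from 0.000327 to 0.168. The mitochondrial genome was called without control replicate 1 (adjusted p = 0.00716 for CCS1477 and 0.0349 for JQ1).

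**Figure D1:**
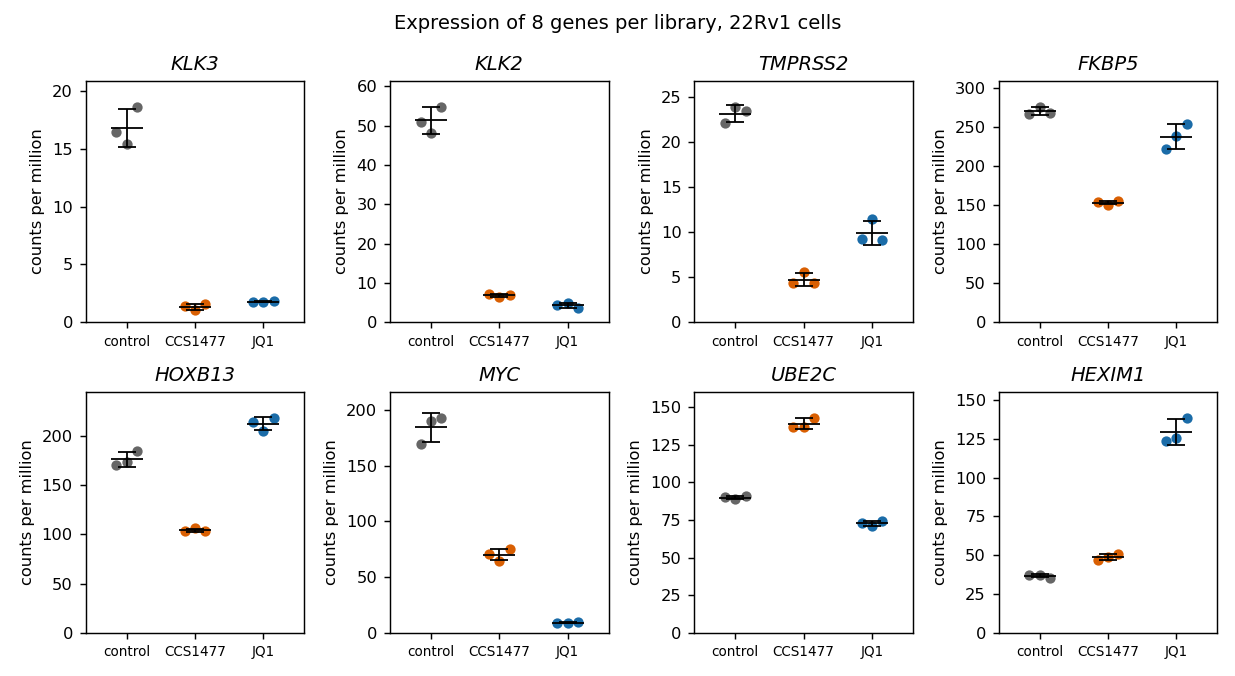
CPM in each of the 9 libraries for 8 genes, with points for the 3 libraries of a group, a horizontal bar for their mean and whiskers for 1 SD. KLK3 averaged 16.8 CPM in control, 1.3 under CCS1477 and 1.75 under JQ1, and MYC averaged 184, 70.2 and 9.18 CPM.

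The second comparison asked the same of the BET inhibitor. JQ1 lowered MYC from 184 ± 13 to 9.18 ± 0.74 CPM (log2 change -4.33 ± 0.07, a 20.1-fold fall), and 54 of 57 measured MYC targets fell with 0 rising. KLK2 (-3.58 ± 0.09) and KLK3 (-3.26 ± 0.12) fell again, and KLK4 fell by 2.13. HEXIM1, an inhibitor of the elongation factor P-TEFb and a marker of BET inhibition, rose 3.52-fold from 36.7 ± 0.9 to 129 ± 8 CPM. DNA replication genes fell in 31 of 42 cases.

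For MYC targets the counts were 0 higher and 55 lower adjusted over the list alone, with a median of -0.68 (adjusted p = 1.11e-17, and 0.328 with an estimated correlation). The folate carrier gene SLC19A1 (-3.08), NOP16 (-1.61), NOLC1 (-0.90) and the helicase subunit gene MCM5 (-1.21) were examples. DNA replication genes had 4 that rose beside the 31 that fell (4 and 31 adjusted over the list alone), with E2F2 at -1.69 and MCM2 at -1.03 (adjusted p = 5.95e-07, and 0.363 with an estimated correlation). Homologous recombination genes fell in 24 and rose in 5 of 38 cases (24 and 5 adjusted over the list alone), with RAD51D at -2.01 and RMI2 at -1.05 (adjusted p = 0.00731, and 0.414 with an estimated correlation). The mitosis list was not called (19 rose, 11 fell of 40, the same adjusted over the list alone; adjusted p = 0.178), with BUB1 at 0.73 and PRC1 at -0.58.

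The broad androgen response list was not called (38 up, 48 down of 97, and 39 and 48 adjusted over the list alone; adjusted p = 0.430). INPP4B (-2.56), PMEPA1 (-1.68) and TMPRSS2 (-1.22) fell, FKBP5 had a smaller fall (-0.19), and SAT1 (2.12) and MAF (1.66) rose. Androgen metabolism genes fell in 13 and rose in 2 of 15 cases (13 and 2 adjusted over the list alone; median -1.02, adjusted p = 0.000596, and 0.363 with an estimated correlation), including UGT2B10 (-2.31), AKR1C2 (-2.24) and UGT2B15 (-1.51). FOXA1 (0.25) and HOXB13 (0.27) rose. With library totals only, FKBP5 had a log2 change of -0.30, FOXA1 of 0.14 and HOXB13 of 0.15. The luminal list was not called (6 up, 11 down of 22; adjusted p = 0.540), with ELF3 at 0.83 and GATA2 at -0.95.

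Interferon-response genes fell in 21 and rose in 11 of 39 cases (21 and 11 adjusted over the list alone; adjusted p = 0.0309, and 0.363 with an estimated correlation). DTX3L (-2.71), OAS3 (-2.64) and PARP9 (-2.11) fell, while the regulators IRF7 (1.62) and STAT2 (0.84) rose. Genes of the ATF4 and amino acid response fell in 23 and rose in 4 of 33 cases (23 and 4 adjusted over the list alone), with NUPR1 at -1.81, SLC7A11 at -1.61 and ATF3 at 1.46 (adjusted p = 1.98e-06, and 0.363 with an estimated correlation). Among p53 targets 13 of 24 fell and 8 rose (13 and 8 adjusted over the list alone; adjusted p = 0.0104, and 0.422 with an estimated correlation), with SPATA18 at -2.25, GDF15 at -2.16 and CDKN1A at 0.52.

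Lists called upward were cholesterol synthesis (18 up, 5 down of 26; adjusted p = 9.50e-05, and 0.365 with an estimated correlation), histones (13 up, 2 down of 21; adjusted p = 0.0104, and 0.422 with an estimated correlation) and markers of BET inhibitor response (4 up, 2 down of 7; adjusted p = 0.00751, and 0.340 with an estimated correlation). Their counts were the same when adjusted over the list alone. The histone and marker lists have some histone genes in common. INSIG1 (1.45) and MVD (1.49) of sterol metabolism, the linker histone gene H1-10 (0.99) and SERPINI1 (1.51) were examples, and ZMYND8 of the marker list fell by 0.91. BRD2, which encodes a BET protein, rose by 0.78. The remaining lists were not called: immediate early genes (16 up, 9 down of 29; adjusted p = 0.125; JUND 1.71, JUN 1.39), the BCL2 family (8 and 8 of 17; 0.735; BOK -2.76, BCL2 -1.33, MCL1 0.67), NF-kappaB and TNF response (5 up, 9 down of 22; 0.209; LIF -4.68, CFLAR -1.71), hypoxia (8 up, 9 down of 25; 0.800; median 0.04, mean -0.02), neuroendocrine markers (5 up, 10 down of 18; 0.175; SYT4 -1.45), basal markers (1 up, 4 down of 9; 0.806), mesenchymal markers (4 up, 6 down of 14; 0.663), leukocyte markers (0 up, 2 down of 4; 0.430), ribosomal proteins (30 up, 6 down of 75; 0.209), the mitochondrial genome (10 up, 0 down of 13; 0.208) and transcription elongation and bromodomain genes (16 up, 5 down of 30; 0.108; KAT2A -1.54). Adjusted over the list alone, the counts of the lists not called were the same except for hypoxia (9 up, 9 down), the BCL2 family (8 up, 9 down), basal markers (1 up, 3 down), ribosomal proteins (25 up, 6 down) and the mitochondrial genome (11 up, 0 down).

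By the same limits on level and overlap the largest rises were in TMEM105 (4.13 ± 0.19), EFR3B (3.76), PCP4L1 (3.60), IQCN (3.26), the RNA-editing enzyme gene ADARB1 (3.21), MIR7-3HG (3.17), PEG10 (3.10) and the calcium channel gene ITPR1 (3.09). PEG10, a retrotransposon-derived gene, was the most abundant of these, going from 601 ± 23 to 5164 ± 123 CPM. CYP2C8 (-5.65 ± 0.25), LIF (-4.68 ± 0.27), P2RX5 (-4.12), BCAT1 (-3.91), SH3TC1 (-3.91), the hepatocyte growth factor gene HGF (-3.82) and DTX3 (-3.80) fell most beside MYC. CYP2C8 and LIF averaged 0.191 and 0.181 CPM under JQ1, so the size of their falls rests on few reads. P2RX5 shares 41.6% of its exon bases with the read-through gene P2RX5-TAX1BP3 on the same strand.

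In all, 12994 genes changed under JQ1 (6616 higher, 6378 lower), and 3511 changed at least 2-fold, 1090 upward and 2421 downward. With library totals as the only scaling the median of all genes moved from 0.01 to -0.10 and the split was 4938 higher and 7444 lower. The interferon response call was lost without JQ1 replicate 2 (adjusted p = 0.0568) and among protein-coding genes alone (0.0985), and over the alternatives that used camera this adjusted p ran from 0.0102 to 0.363.

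**Figure D2:**
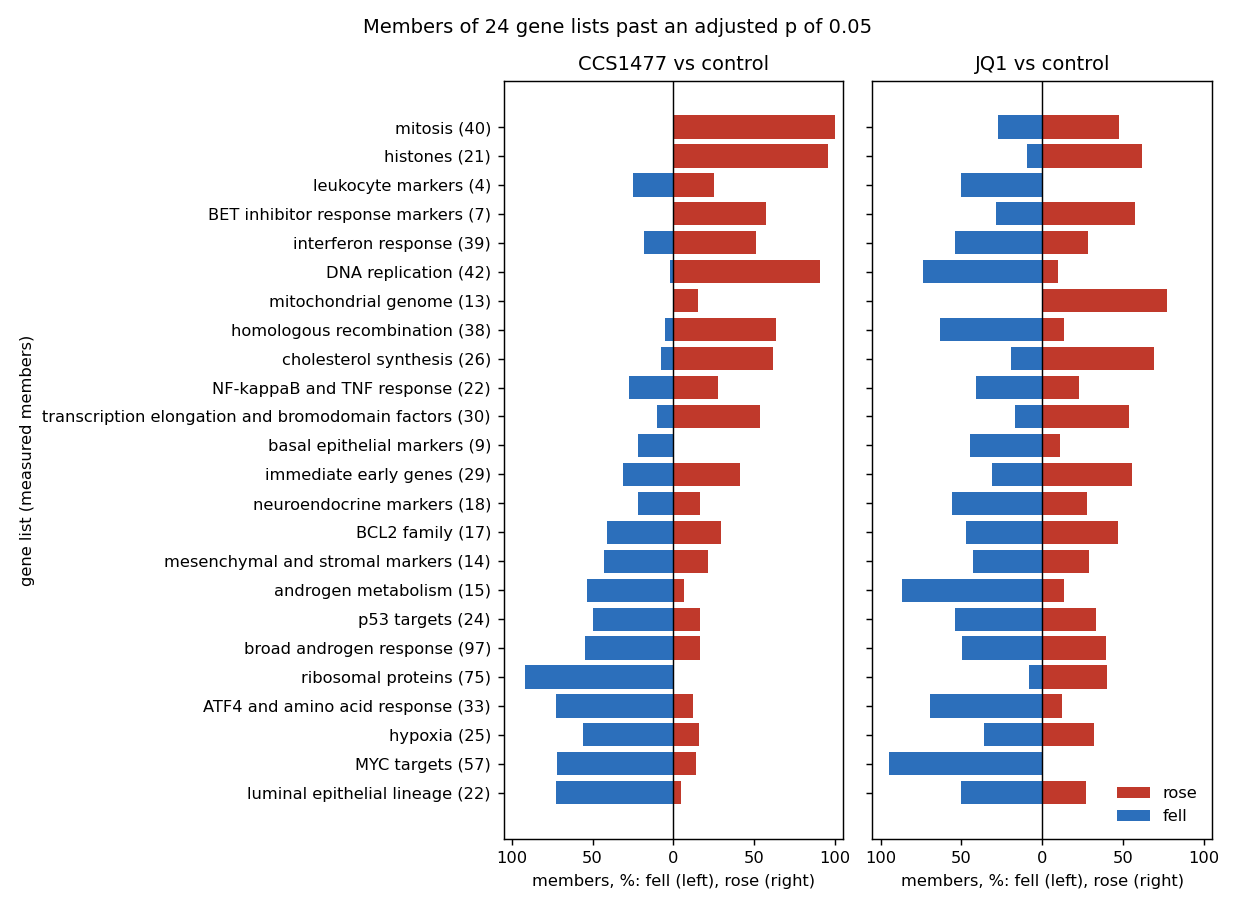
Percent of the measured members of 24 gene lists that rose (red, right) or fell (blue, left) at an adjusted p under 0.05 under CCS1477 and under JQ1, each against control, with the number of measured members after each list name. All 40 mitosis genes rose under CCS1477, and 54 of 57 MYC targets fell under JQ1.

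The third comparison set the inhibitors against each other at these doses, which differ (96 nM and 100 nM). MYC was 7.66-fold higher under CCS1477 than under JQ1 (log2 difference 2.94 ± 0.07). TMPRSS2 (-1.06 ± 0.11) and FKBP5 (-0.63 ± 0.04) were lower under CCS1477. KLK2 was higher (0.66 ± 0.11), and KLK3 had a difference of -0.44 ± 0.20 that missed the threshold (adjusted p = 0.0602). The difference of KLK3, CCS1477 vs JQ1, was called with the replicate block (adjusted p = 0.0393), without control replicate 3 (0.0494) and without CCS1477 replicate 3 (0.0298), and the adjusted p ran up to 0.363, without CCS1477 replicate 2, where the difference was -0.24. All but 1 of 42 DNA replication genes were higher under CCS1477.

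DNA replication genes (41 higher, 1 lower of 42, the same adjusted over the list alone) had a median difference of 0.72 (adjusted p = 7.50e-26, and 0.0562 with an estimated correlation), with E2F2 at 1.81, MCM5 at 1.43 and MCM2 at 1.35. Mitosis genes were higher in 32 and lower in 1 of 40 cases (34 and 1 adjusted over the list alone), with FOXM1 at 1.33, PRC1 at 1.13 and UBE2C at 0.94 (adjusted p = 3.36e-10, and 0.160 with an estimated correlation). MYC targets were higher in 41 and lower in 4 of 57 cases (adjusted p = 2.14e-08, and 0.263 with an estimated correlation), and homologous recombination genes in 29 and 2 of 38 (adjusted p = 1.40e-08, and 0.116 with an estimated correlation). Both counts were the same adjusted over the list alone. The broad androgen response list was lower in 55 and higher in 23 of 97 (58 and 24 adjusted over the list alone; adjusted p = 0.000134, and 0.0658 with an estimated correlation). Luminal genes were lower in 14 and higher in 4 of 22 cases (14 and 5 adjusted over the list alone), among them ELF3 (-1.47), HOXB13 (-1.03) and CDH1 (-1.01), the E-cadherin gene (adjusted p = 3.33e-06, and 0.125 with an estimated correlation).

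Interferon-response genes were higher under CCS1477 in 24 and lower in 7 of 39 cases (25 and 7 adjusted over the list alone; median 1.06, adjusted p = 1.10e-05, and 0.0658 with an estimated correlation). OAS3 (3.70), PARP14 (2.80) and DTX3L (2.52) were examples. Among the 18 members with a control mean of at least 5 CPM the median difference was 0.17, with 9 higher and 5 lower, and among the other 21 it was 1.41, with 15 higher and 2 lower. Leukocyte markers were higher in 3 and lower in 0 of 4 measured cases (3 and 0 adjusted over the list alone; adjusted p = 0.388). Ribosomal protein genes were lower in 71 and higher in 0 of 75 cases (71 and 0 adjusted over the list alone; median -0.29, adjusted p = 3.33e-06, and 0.460 with an estimated correlation). Smaller calls were made for the ATF4 response (18 higher, 7 lower of 33; adjusted p = 0.0166, and 0.488 with an estimated correlation), immediate early genes (5 and 16 of 29; adjusted p = 0.0311, and 0.299 with an estimated correlation), cholesterol synthesis (9 and 15 of 26; adjusted p = 0.0321, and 0.552 with an estimated correlation), histones (15 and 3 of 21; adjusted p = 0.0377, and 0.501 with an estimated correlation), hypoxia (6 and 15 of 25; adjusted p = 0.0432, and 0.330 with an estimated correlation) and androgen metabolism (11 and 2 of 15; adjusted p = 0.0457, and 0.406 with an estimated correlation). Adjusted over the list alone, these counts were the same except for the ATF4 response (19 and 8), histones (15 and 4) and hypoxia (6 and 17). Of the lists not called, the BCL2 family had a median of -0.14 and a mean of 0.14, basal epithelial markers a median of 0.16 and a mean of -0.10, and mesenchymal and stromal markers a median of -0.05 and a mean of 0.03, and the test pointed up for each.

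By the same limits the genes with the largest differences upward were DTX3 (4.53), LIF (4.34), ODAD2 (3.78), ZNF532 (3.76), OAS3, P2RX5 (3.70), SLITRK5 (3.54) and GALC (3.53). Those with the largest differences downward were TMEM105 (-3.69), ITPR1 (-3.23), ADARB1 (-3.21), the metallothionein gene MT1X (-2.98), MIR7-3HG (-2.85), LVRN (-2.83), AHNAK2 (-2.71) and TMEM132B (-2.64). In all 12525 genes differed (6045 higher and 6480 lower under CCS1477), 2955 of them at least 2-fold (1967 and 988). With library totals as the only scaling the median of all genes moved from -0.02 to 0.14, and these became 7822 and 4184, and 2514 and 662. The hypoxia call was lost with upper-quartile factors (adjusted p = 0.0548), library totals only (0.131), the filter of 10 counts (0.0506), the 2 groups alone (0.0629), the replicate block (0.0503) and protein-coding genes alone (0.0795), and without JQ1 replicate 1 (0.0522) or CCS1477 replicate 2 (0.0612). Androgen metabolism was lost with the filter of 10 counts (0.0522), the 2 groups alone (just above the threshold) and protein-coding genes alone (0.105), and without JQ1 replicate 1 (0.0692) or CCS1477 replicate 1 (0.0601). Cholesterol synthesis was lost with library totals only (0.151), the 2 groups alone (0.0629) and without JQ1 replicate 1 (0.0522). Histones were lost with protein-coding genes alone (0.0565) and without JQ1 replicate 1 (0.0692), and immediate early genes with protein-coding genes alone (0.0512). Over the alternatives that used camera, the estimated correlation included, the adjusted p ran from 0.00759 to 0.330 for hypoxia, 0.00113 to 0.406 for androgen metabolism, 0.00673 to 0.552 for cholesterol synthesis, 8.12e-05 to 0.501 for histones and 0.00379 to 0.299 for immediate early genes.

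Changes under the inhibitors were then set side by side gene by gene. Of 666 genes at least 2-fold lower under CCS1477, 528 (79.3%) were also lower under JQ1 and 17 were higher. Of 198 genes at least 2-fold higher under CCS1477, 104 (52.5%) were higher under JQ1 and 22 were lower. In total 4974 genes changed in the same direction (2376 higher and 2598 lower in both), where independent lists of these sizes would share 1422 and 1322. Another 1608 went opposite ways, 946 higher under CCS1477 and lower under JQ1 and 662 the reverse, where independent lists would give 1370 and 1372. HOXB13 and CDKN1A were lower under CCS1477 and higher under JQ1, and UBE2C, E2F1, NR3C1 and CREBBP were higher under CCS1477 and lower under JQ1. The fall of CREBBP under JQ1 (-0.21) was lost without JQ1 replicate 2 (-0.17, adjusted p = 0.0831). The comparisons share their control libraries. In the simulation all 9 libraries were drawn anew without effects, and the simulated controls served both comparisons. The mean there was 0.400 genes higher and 0.150 lower in both. With no gene changed, few calls could arise, so these counts do not measure what shared controls add where many genes change. Part of the excess may come from the shared controls. The correlation of log2 changes across genes, which are not independent replicates, was 0.455, against 0.505 in the simulation, and the covariance was 0.182 against 0.0169, a difference of 0.165.

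**Figure D3:**
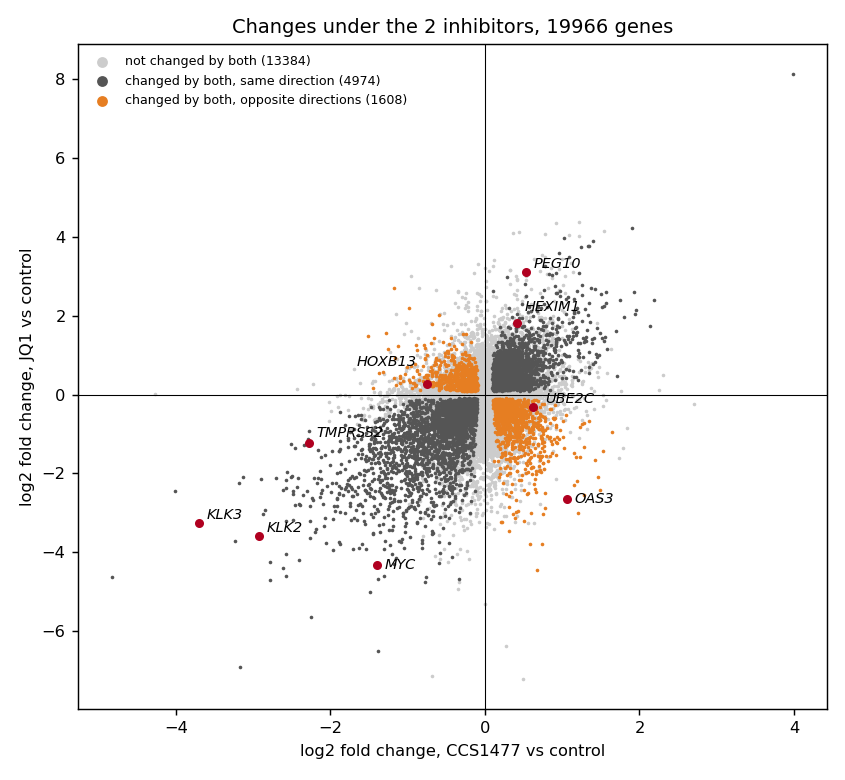
Log2 fold change under CCS1477 (horizontal axis) and under JQ1 (vertical axis), each against control, for 19966 genes, with 4974 genes that changed in the same direction in dark grey, 1608 that changed in opposite directions in orange and named genes in red. MYC lies at -1.39 and -4.33, and OAS3 at 1.06 and -2.64.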

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

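The tests of scaling, of the library richest in mitochondrial ribosomal RNA, of DNA replication genes beside mitosis genes and of leukocyte markers were chosen only after the result was seen. Several results drew attention because the effects of the inhibitors went opposite ways, with the difference itself past the threshold in the direct comparison. As CCS1477 minus JQ1 on the log2 scale, HOXB13 differed by -1.03 and CDKN1A by -0.87, each lower under CCS1477 and higher under JQ1. UBE2C differed by 0.94, E2F1 by 0.93, NR3C1 by 0.69 and CREBBP by 0.49, each higher under CCS1477 and lower under JQ1. Among gene lists the median difference was 0.72 for DNA replication, 0.39 for homologous recombination and 1.06 for interferon response, and none of these 3 list calls held with an estimated correlation (adjusted p = 0.0562, 0.116 and 0.0658). The estimated correlations were 0.183, 0.120 and 0.0326, and how far they account for the lost calls was not tested.

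Mitosis and DNA replication genes rose together under CCS1477. All 40 mitosis genes rose under each of 4 scalings, under which the median of all genes lay only between 0.01 and 0.06. Scalings this close could not have removed the rise, so they show only that the choice among them is not the cause. A larger shift was not tested. Without CCS1477 replicate 1, 39 of the 40 rose, which argues against that library as the cause. The list median of 0.56 lay at percentile 100 of 10000 random lists matched on GC content, transcript length and expression, whose central 95% ran from -0.09 to 0.06. These random lists take no account of the correlation between members, so their range is likely too narrow. By camera with an estimated correlation the list kept its call (adjusted p = 0.0143). A build-up of cells in mitosis alone is argued against by the 38 DNA replication genes that rose as well. A larger share of cycling cells under CCS1477, or higher transcription per cycling cell, may account for the pattern, and the counts cannot tell these apart.

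Interferon-response genes differed between the inhibitors by a median of 1.06 at the lowest over 4 scalings, the value with TMM factors. The other scalings raised the median of all genes, from -0.02 with TMM to 0.14 with library totals only, and so could not lower this difference. They show only that the choice among them is not its cause. Leukocytes stay open: CD4, the most abundant leukocyte marker measured (3.52 CPM in control), changed by -1.30 under CCS1477 against control but by 0.74 against JQ1, and 3 of the 4 markers measured of 20 were higher than under JQ1 and 0 lower (median 1.04). Few reads stay open too: among the 18 members with at least 5 CPM in control the median difference was 0.17, under the bound of 0.5 written for few reads before the test. The members went both ways there (9 higher, 5 lower), so that this median decides nothing for single genes, and OAS3, at 12.4 CPM in control, differed by 3.70. Opposite responses of some members to the inhibitors may account for these genes, which stays a hypothesis.

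For ribosomal protein genes under CCS1477 the list median of -0.20 lay at percentile 0 of matched random lists (central 95% from -0.08 to 0.03), which take no account of the correlation between members, and the list had an adjusted p = 0.356 with an estimated correlation. The lowest number that fell over 4 scalings was 50 of 75, with library totals only. The upper quartile of the members was then -0.12, the highest over the 4 scalings, and it was -0.16 with TMM factors. The median of all genes lay only between 0.01 and 0.06 under these scalings, too close to have removed the fall. They show only that the choice among them is not the whole cause, and a larger shift was not tested.

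The 6 libraries of a comparison can be split 3 against 3 in 10 ways, too few for a share under 0.05. For CCS1477 against control the real split gave 8214 genes changed and 834 at least 2-fold, the highest other split 0 and 0, so that 1 of the 10 splits gave as many. For JQ1 against control the real split gave 12617 and 3277 and the highest other 0 and 0 (1 of 10), and for CCS1477 against JQ1 12363 and 2791 and the highest other 0 and 0 (1 of 10). Gene lists called numbered 17 in the real split of CCS1477 and control libraries with 13 in the highest other (1 of 10), and 11 with 10 for JQ1 and control (1 of 10). For CCS1477 and JQ1 libraries they numbered 12 with 13 in the highest other, and 3 of the 10 splits gave at least as many. These fits used only the 6 libraries compared. Each other split puts libraries of both groups on each side, so that the difference between the groups counts there as spread within a side. With so many genes changed, counts of 0 genes in those splits could hardly have been otherwise, and they say nothing about chance.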

How the results depend on the processing

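The restriction to protein-coding genes was chosen only after the data were seen. Of 6711 gene values under alternatives (354 genes and comparisons), 6647 kept their direction and side of the threshold, 39 lost the call, 20 gained it and 5 changed sign. With library totals only, the sign turned for FOXA1, CCS1477 vs control (0.0137), CCND1, CCS1477 vs control (0.00609) and EP300, CCS1477 vs JQ1 (0.101). With a library left out, values ran from -0.109 to 0.00403 for EP300, CCS1477 vs JQ1 and from -0.0489 to 0.186 for CSF1R, CCS1477 vs JQ1. None of these was called with all libraries, and the cause was not tested. Genes changed numbered 7011 (DESeq2) to 8457 for CCS1477 against control, 10507 (protein-coding genes) to 13488 (no filter) for JQ1 against control, and 10246 to 12791 for CCS1477 against JQ1. With an estimated correlation 6, 0 and 0 lists were called, and the cause was not tested. For JQ1 fry, which asks whether genes of a list move one way without comparing them with others, called 23, and 24 with the replicate block. Genes changed at least 2-fold in the same direction by both inhibitors numbered 516, fewer than without that limit because the threshold is stricter. Another 20 changed at least 2-fold under both in opposite directions. With the replicate number as a block, genes changed numbered 8379, 12944 and 12491 and lists 17, 11 and 14. The block ended the call of hypoxia, CCS1477 vs JQ1, and added those of KLK3, CCS1477 vs JQ1, and of MT-ND1 and MT-ATP8, CCS1477 vs control, with no other list or named gene changing its call. Over all tested genes same-numbered libraries correlated by -0.0451 to 0.0850. Above 4 CPM the same-numbered control and JQ1 libraries correlated by 0.223 to 0.275, against -0.245 to 0.00369 for other numbers, while same-numbered pairs with a CCS1477 library ran from -0.187 to 0.0968, and 6 of 9 libraries were closest to their own number. Replicate 2 had the lowest share of mitochondrial ribosomal RNA in each group (0.490% in control, 0.631% under CCS1477 and 0.516% under JQ1). The numbers were not taken to pair all 9 libraries, and a pairing of control with JQ1 libraries stays open. Without a filter beyond 1 count 19, 15 and 16 lists were called. That setting added mesenchymal and stromal markers and the mitochondrial genome for CCS1477, immediate early genes, luminal epithelial lineage, the mitochondrial genome and transcription elongation and bromodomain factors for JQ1, and neuroendocrine markers for the direct comparison. Genes near 1 CPM carry the least precise changes.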

Other observations

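The gene families were chosen after their values were seen, whereas the tests of neighbouring genes and of gene span were written before their results. Clustered protocadherins, cell-surface adhesion genes encoded side by side on chromosome 5, were counted by cluster, without a test between clusters. Under JQ1, 11 of 13 measured genes of the beta cluster fell and 0 rose (median log2 change -1.57), with PCDHB6 at -3.23 and PCDHB13 at -2.65. In the alpha cluster 13 of 15 fell and 1 rose (median -1.05), PCDHA13 at -1.77 and PCDHAC2 at 0.51, although alpha genes share exons at their 3' end and their counts are uncertain. In the gamma cluster, whose genes also share 3' exons, 6 of 19 fell and 1 rose (median -0.32). Under CCS1477 the counts were 1 lower and 0 higher in the alpha, 1 lower and 1 higher in the beta and 1 lower and 2 higher in the gamma cluster. In the direct comparison 13 of 15 alpha genes were higher under CCS1477 and 1 lower (PCDHAC2, -0.90), 11 of 13 beta genes were higher and 0 lower, and 8 of 19 gamma genes were higher and 0 lower.

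Metallothioneins, small metal-binding proteins, rose under JQ1 in 4 of 4 measured cases (median 2.39): MT1X by 2.63, MT2A by 2.29 and MT1G by 1.26 among them. Under CCS1477, MT1E (0.53) and MT2A (0.48) rose. Of 9 measured HOXA genes, 6 fell and 0 rose under JQ1 and 3 rose and 0 fell under CCS1477, and of 9 HOXB genes 6 fell and 2 rose under JQ1 and 2 fell and 1 rose under CCS1477. The directions of these families under JQ1 held under each of 4 scalings.

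Tested protein-coding genes that followed each other along a chromosome tended to fall together. No limit was set on the distance within such an adjacent pair, and genes that were not tested or not protein-coding could lie between. Under CCS1477, 58 of 13996 adjacent pairs had both genes at least 2-fold lower, against a mean of 13.2 in 10000 random placements of the same calls (permutation p = 0.0001, the smallest they can give), and 343 did under JQ1 against 216. Without pairs that share the first 3 letters of their symbols 42 and 278 remained in the count (random means 12.5 and 204). Without pairs on 1 strand or with overlapping spans 20 and 126 remained (5.25 and 85.6). Placements among genes of similar mean expression gave means of 13.7 and 222. These values argue against overlapping exons and against expression level as the whole cause, each taken alone, as the limits were not applied together. The letter rule kept pairs with related names, such as MX2 with MX1 under JQ1 and ABHD14A-ACY1 with ACY1 under both inhibitors. Paralogs were therefore only partly removed and stay open. Pairs under CCS1477 included TSPAN8 with LGR5 (-1.38 and -1.32) and MYCL with MFSD2A (-1.04 and -1.10). A shared regulatory region that loses activity may account for such pairs, and no measurement here tests it.

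The hypothesis that longer genes fall more under JQ1 was not borne out by the medians of the longest and shortest genes: the median log2 change of the genes with the longest genomic spans (2804 genes) was 0.02 and that of the genes with the shortest (2805 genes) was -0.07, a difference of 0.0826 in the other direction. The share of genes at least 2-fold lower was 14.8% among the longest, 14.0% among the shortest and between 10.4% and 11.8% in the 3 groups between, whose medians were 0.02, 0.04 and 0.07.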
